A study of Mus musculus with 15 samples.

How the data were processed

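The series holds 15 RNA-seq libraries of mouse colon cancer organoids of the AKP genotype (mutant Apc and Trp53 among others), grown in C57Bl6 recipient mice and cultured again. Libraries were grouped by the sample titles into 5 groups of 3 replicates: organoids from liver metastases of transplant rounds 1 to 3 (Met1, Met2, Met3) and organoids from primary tumours of rounds 2 and 3 (Primary2, Primary3). The labels name a PureLink RNA Mini kit and a NEBNext Ultra II Directional preparation with poly(A) selection. They do not say whether replicates of a group are separate mice, separate organoid lines or separate cultures of 1 line, so p-values measure only the spread between these samples. Sequencing batch and date are not given in the sources used here.

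Per the submitters' processing notes the authors quantified reads with Salmon 1.3.0 on mm10. The deposited table holds gene-level estimated counts for 54418 Ensembl gene IDs, all of them whole numbers (0 values with a fractional part). How transcripts were summed to genes, the annotation release, the rounding and any filter are not given in the sources used here. Gene symbols and positions were taken from GENCODE M21 (GRCm38, equal to mm10), which matched 54096 IDs. The remaining 322 IDs hold 0.0342% of the counts and stayed in the table under their IDs. Each of the 15 columns was matched through the library name in its sample's description, with 0 columns left over.

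The floor for genes with no count on one side, 3 counts over the group, equals 0.141 to 0.212 CPM per library before TMM scaling. Other CPM values use the TMM-scaled library size. Any count was found for 32481 genes. edgeR's filterByExpr by group kept 14925 genes with 99.9% of the counts and removed 39493. The common dispersion was 0.118, a coefficient of variation between replicates of 0.343. In counts simulated from these libraries, the metastasis against primary comparison recovered 12.2% of genes changed 1.5-fold, 64.6% at 2-fold and 92% at 8-fold. It made 4 false calls among 14404 unchanged genes. The recovered shares were 6.12%, 37.5% and 80% for Met3 against Met1 and 0%, 8% and 67.3% for the difference between rounds. Replicates varied most in Met2, and whether these rates hold there was not tested.

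Genes were tested with edgeR 4.0.16 (TMM factors, quasi-likelihood fit and F test, group means, all 15 libraries in one fit) under R 4.3.3. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Fold changes are fitted log2 values, and the standard error printed beside each is the log2 change divided by the square root of its F statistic. There were 8 comparisons. The main ones are metastasis against primary (mean of Met2 and Met3 against mean of Primary2 and Primary3, 6 against 6 libraries) and Met3 against Met1. The other 6 are Met2 against Primary2, Met3 against Primary3, the difference between those, Met2 against Met1, Met3 against Met2, and Primary3 against Primary2. Agreement of the rounds was measured by Pearson and Spearman correlation across genes of the fold changes of Met2 against Primary2 and Met3 against Primary3, which share no library. Genes are not independent replicates, so no p-value is attached to that correlation. Principal components were computed on log2 CPM of the 500 most variable genes.

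Where all libraries of the lower side are at 0 counts, the change is given as a lower bound, computed against the floor of 3 counts over that side. Where the lower side holds 1 to 3 counts over all its libraries, the ratio of CPM is given with an exact binomial counting interval. These bounds and intervals cover counting error only, not the spread between samples.

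Named genes were chosen by a fixed rule. Gata6, the gene of the series title, and the engineered genes Apc and Trp53 are given throughout. For each main comparison the 10 genes with the largest positive and the 10 with the largest negative fitted change are named, among genes past the test with an average log2 CPM of at least 1 and with no overlap of the libraries of both sides. For each other comparison 3 and 3 are named by the same rule. Some genes that the rule names are not reported here. Predicted or unnamed genes were passed over, and 1 gene without a symbol was passed over as unnamed, which was decided after its values were seen. From each gene list up to 4 members with the smallest p are named. Sox2, Hnf4a and the other genes in which Met2 replicate 1 stands apart were chosen after their values were seen.

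The 35 gene lists were intestinal stem cell, Wnt target, fetal and regenerative, YAP target, L1cam/Emp1/laminin invasive marker, absorptive enterocyte and colonocyte, goblet cell, Paneth cell, enteroendocrine cell, tuft cell, intestinal transcription factor, gastric and foregut, squamous, mesenchymal transition, epithelial, TGF-beta target, BMP target, MAPK output, antigen presentation by MHC class I, antigen presentation by MHC class II, interferon-stimulated, inflammatory cytokine and chemokine, proliferation, hypoxia and glycolysis, cholesterol synthesis, nuclear genes of oxidative phosphorylation, p53 target, stress and early response, unfolded protein and amino acid response, mitochondrially encoded, and markers of hepatocytes, fibroblasts, endothelial cells, leukocytes and erythroid cells. Each list with at least 5 measured members was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera asks whether a list's members moved more than the other genes, fry whether they moved at all. The lists, the comparisons, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

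The alternatives were median-ratio and upper-quartile factors in place of TMM, no filter on low counts, a filter of CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the groups compared, each library left out in turn, Met1 included among the metastases, a linear trend over Met1, Met2 and Met3, and for lists an estimated correlation and fry. A covariate for the share of ribosomal RNA, and list members counted without 1 library, were added after the data were seen. Such counts are named where they moved by over 1.5 times and reached at least 3, and brackets beside a count of list members hold that adjusted over the list alone. Other explanations were tested with the share of counts on the ribosomal RNA gene CT010467.1, marker genes of other cell types, stretches of 31 bases shared by transcripts of Gata4 and Gata6, genes within 1 Mb of Gata6, and the median fold change of each of 20 chromosomes against 10000 random sets of as many genes. Labels were also exchanged between libraries, in all 10 splits of 3 against 3 and in 100 drawn of the 200 splits within rounds. Python 3.11.15 and matplotlib 3.10.9 were used for tables and figures. Raw reads, splicing, and copy number or sequence variants were not analysed here.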

Results

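The libraries come from AKP organoids, cultured mouse colon tumour cells, recovered from liver metastases in transplant rounds 1, 2 and 3 (Met1, Met2, Met3) and from primary tumours in rounds 2 and 3 (Primary2, Primary3). Each group held 3 libraries, numbered by replicate (rep). Total counts ran from 14122203 (Primary3 rep 1) to 21306543 (Primary2 rep 2). The ribosomal RNA gene CT010467.1, which poly(A) selection should largely remove, took 2.01% to 3.73% of counts in Met1 and 6.24% to 7.52% in Met2. Its share was 3.38% to 4.09% in Met3, 3.74% to 3.83% in Primary2 and 3.53% to 7.03% in Primary3.

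Principal component 1 held 42.9% and component 2 24.9% of the variance of the 500 most variable genes. On component 1, Met2 reps 2 and 3 and the 3 Met3 libraries scored between 40.3 and 59.3, and the 6 primary libraries between -35.7 and -23.6. Met1 scored between 36.5 and 55.2 on component 2, where Met2 rep 1 scored 33.7. That library scored 7.17 on component 1 and lay apart from all others on component 3 at -53.2.

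**Figure D1:**
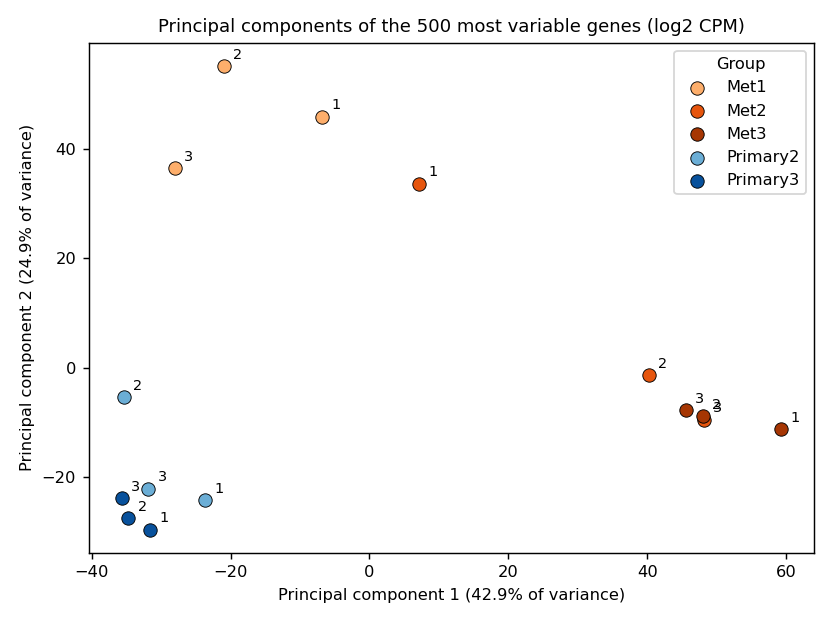
Scores of the 15 libraries on principal components 1 and 2 of the 500 most variable genes (log2 CPM), 1 point per library, coloured by group. Met2 rep 1 lay away from the other Met2 libraries.

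Gata6, the gene of the series title, encodes a zinc-finger transcription factor of the gut epithelium (ENSMUSG00000005836, GRCm38 chromosome 18, 11052064 to 11085635). Its mRNA stood at 18.7 ± 11.6 CPM (SD, n = 3) in Met1, 0.451 ± 0.658 in Met2 and 0.0359 ± 0.0622 in Met3. In Primary2 it stood at 5.14 ± 3.25 and in Primary3 at 7.34 ± 2.56 CPM. It was lower in all 6 later metastasis libraries than in all 6 primary libraries, by a log2 change of -5.45 (SE 0.83, adjusted p = 0.000572). Within round 3 the primary to metastasis ratio was 204 (counting interval 56 to 1690, 351 against 2 counts, adjusted p = 0.00333). Within round 2 the log2 change was -3.49 (SE 0.99, adjusted p = 0.0393). Met1 exceeded Met3 by a ratio of 512 (141 to 4230, adjusted p = 0.00205), and Met2 differed from Met1 by -5.35 (SE 1.05, adjusted p = 0.00995). No difference passed the test between Met3 and Met2 (-3.41, SE 1.44, adjusted p = 0.3), between the primaries (0.51, SE 0.84, adjusted p = 0.935) or between rounds (-3.92, SE 1.68, adjusted p = 0.38).

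The adjusted p of the round 2 difference of Gata6 ran from 0.0027 to 0.172 over the alternatives. It was lost without any 1 of the 6 libraries but Met2 rep 1 (0.0596 to 0.115). It was also lost with the replicate block (0.0678), the ribosomal covariate (0.131), limma-voom (0.109) or only the groups compared (0.172). The difference of Gata6 between Met2 and Met1 ran from 8.49e-07 to 0.0854 and was lost with the covariate (0.0633) or only the groups compared (0.0854).

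Apc, the negative regulator of Wnt signalling that is mutated in these organoids, lies on the same chromosome (ENSMUSG00000005871, chromosome 18, 34220924 to 34322552). Its mRNA was 42.7 ± 7.28 CPM in Met2 and 47.3 ± 1.18 in Met3 (n = 3 each), against 76.7 ± 7.50 in Met1, 85.0 ± 6.67 in Primary2 and 68.8 ± 7.14 in Primary3. It fell in metastasis against primary (log2 -0.77, SE 0.09, adjusted p = 0.000174) and in Met3 against Met1 (-0.70, SE 0.13, adjusted p = 0.00417). It also fell in Met2 against Primary2 (-0.99, adjusted p = 0.00187), Met3 against Primary3 (-0.54, adjusted p = 0.016) and Met2 against Met1 (-0.84, adjusted p = 0.00525). The first of these 3 calls ended with only the groups compared (0.0501, range 1.15e-09 to 0.0501). The second ended without Met3 rep 1 (0.064) or Primary3 rep 1 (0.0602, range 0.00168 to 0.064). The last ended with the covariate (0.0816) or only the groups compared (0.071, range 3.23e-07 to 0.0816).

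Trp53, the mutated tumour suppressor (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), fell in metastasis against primary by 0.51 on the log2 scale (SE 0.16, adjusted p = 0.0312), with libraries of both sides overlapping. That call of Trp53 was lost without Met2 reps 2 (0.0789) or 3 (0.0743), Met3 reps 1 (0.0929) or 2 (0.0647), Primary2 rep 3 (0.0732) or Primary3 reps 1 (0.079) or 3 (0.0562). It was also lost with no low-count filter (0.141), over a range of 0.00417 to 0.141. In the other comparisons between groups Trp53 did not pass, with log2 values from -0.60 (Met2 against Primary2, adjusted p = 0.105) to 0.65 (Met3 against Met1, adjusted p = 0.0582). The latter passed without Met1 rep 1 (0.0413), with the ribosomal covariate (0.0178) or with DESeq2 (0.0232), over a range of 0.0178 to 0.272.

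Gata4, a paralog of Gata6 (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692), moved the other way. It stood at 4.94 ± 6.69 CPM in Met2 and 13.8 ± 7.33 in Met3 (n = 3 each), and at 0.0167 in Met1, 0.0853 in Primary2 and 0.0449 in Primary3. It rose in metastasis against primary (log2 6.95, SE 1.16, adjusted p = 0.00101), although Met2 rep 1 held 0 counts of Gata4. With Met1 counted among the metastases the adjusted p was 0.14 (range 2.54e-08 to 0.14). Met3 exceeded Met1 by a Gata4 ratio of 838 (150 to 33100, adjusted p = 0.00497) in 3 of 3 libraries.

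**Figure D2:**
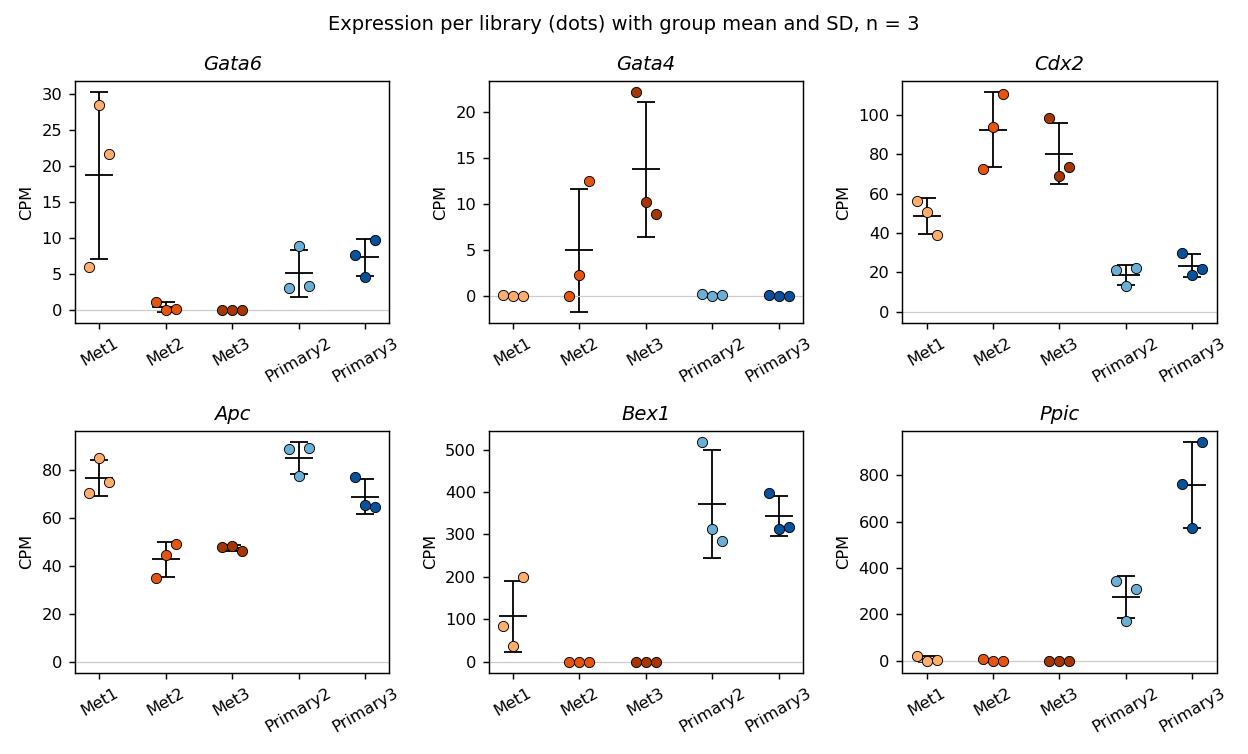
CPM of Gata6, Gata4, Cdx2, Apc, Bex1 and Ppic in each library, with the mean and SD of each group (n = 3). Gata6 averaged 0.0359 CPM in Met3 against 18.7 in Met1.

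Among the genes that fell most in metastasis against primary (6 against 6 libraries) was Bex1, a signalling adaptor. It averaged 372 ± 127 CPM in Primary2 and 343 ± 47.7 in Primary3. Over Met2 and Met3 it came to 2 counts, a ratio of 17600 (counting interval 4870 to 145000, adjusted p = 2.44e-06). Met1 held 106 ± 83.2 CPM. Bex1 lies on chromosome X (ENSMUSG00000050071, 136213972 to 136215513). Tlx1, a homeobox transcription factor of the spleen, held 0 counts in Met2 and Met3 and was at least 729-fold lower (adjusted p = 2.83e-05). Ppic, the secreted-pathway cyclophilin C, fell by 10.56 on the log2 scale (SE 1.18, adjusted p = 9.77e-05) from 275 ± 92.2 CPM in Primary2 and 760 ± 185 in Primary3. Timp3, which inhibits matrix metalloproteinases, fell by 9.55 (SE 0.87, adjusted p = 2.97e-05), and the water channel Aqp1 by 9.20 (SE 0.69, adjusted p = 7.12e-06). Efemp1, an extracellular matrix fibulin, was at least 265-fold lower (adjusted p = 0.000409). Ratios were 2150 (386 to 85100) for the scavenger receptor Scara3 and 948 (324 to 4600) for the galactosyltransferase Ggta1. They were 620 (171 to 5120) for the AP-2 factor Tfap2b and 666 (119 to 26300) for the endocytic receptor Lrp2, with adjusted p of 0.000685 or less for these 4 genes.

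Of the genes with the strongest rises all but Fundc2 averaged 0.250 CPM or less in Primary2 and in Primary3. Ryr3, a calcium release channel, held 0 counts there and reached 16.7 ± 13.0 CPM in Met3, at least 354-fold higher over Met2 and Met3 (adjusted p = 0.000395). Ffar4, a receptor for long-chain fatty acids, rose by a log2 of 9.15 (SE 1.09, adjusted p = 0.000141), and the ion-transport kinase Stk39 by 8.52 (SE 1.10, adjusted p = 0.000215). Clip4, a microtubule linker, rose by 7.94 (SE 1.09), the polysialyltransferase St8sia4 by 7.42 (SE 1.12), the calcium channel subunit Cacna2d1 by 6.86 (SE 1.15) and the EGF-family ligand Epgn by 6.14 (SE 0.95). Adjusted p of these 4 ran from 0.000327 to 0.00107. Dach1, a transcriptional cofactor, rose by 6.13 (SE 1.19, adjusted p = 0.0024), and Fundc2, a protein of the outer mitochondrial membrane, by 6.70 (SE 1.19, adjusted p = 0.00147), although Primary3 rep 3 held 6.539 CPM of Fundc2. Xlr3a, from an X-linked family of near-identical genes among which short reads are hard to place, had a ratio of 3100 (556 to 123000, adjusted p = 0.00965). With limma-voom the adjusted p was 0.199 for Xlr3a (range 8.34e-14 to 0.199), 0.0596 for Fundc2 (7.81e-06 to 0.0596) and 0.0539 for Stk39 (6.67e-13 to 0.0539).

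In all, 4537 of 14925 genes differed in this comparison, 2136 higher and 2401 lower in metastasis. Of these, 1841 differed at least 2-fold (828 higher, 1013 lower), and 1776 had no overlap between the 6 and 6 libraries. Leaving out 1 library gave 3656 (Met3 rep 1) to 5265 genes (Met2 rep 1).

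Target genes of YAP, the transcriptional coactivator of wound repair and mechanical signals, fell as a group in metastasis against primary. Of 20 measured, 12 fell and 0 rose [12 and 1 adjusted over the list alone], with a median log2 change of -0.92 (adjusted p = 0.000337). Ankrd1 fell by 7.01 (SE 0.70), and the matricellular proteins Ccn1 and Ccn2 by 2.55 (SE 0.44) and 2.56 (SE 0.46). Inflammatory cytokines and chemokines fell too, 10 of 20 lower and 0 higher [10 and 1] (median -1.08, adjusted p = 0.00426). The myeloid growth factor Csf2 fell by 5.19 (SE 0.60) and the neutrophil chemokine Cxcl5 by 3.77 (SE 0.51). Hypoxia and glycolysis genes rose, 10 of 19 higher and 0 lower [10 and 0] (median 0.44, adjusted p = 0.00149). Among them were the glucose transporter Slc2a1 (1.16, SE 0.20) and the glycolytic enzyme Gapdh (0.57, SE 0.11). Hypoxia and glycolysis gave 6 higher without Met3 rep 2 or Primary2 rep 3. For all 3 lists the adjusted p was 0.658 with an estimated correlation, the highest over the alternatives, and the lowest were 1.72e-07, 8.83e-05 and 8.17e-05.

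Of 18 epithelial genes, 8 rose and 1 fell [8 and 1 adjusted over the list alone] (median 0.49, adjusted p = 0.0257). The filament protein Krt8 rose from 1023 ± 260 CPM in Primary2 and 1107 ± 69.7 in Primary3 to 2812 ± 1737 in Met2 and 3676 ± 602 in Met3 (log2 1.60, SE 0.30). The epithelial transcription factor Ovol1 rose by 1.12 (SE 0.22). Cdh1, the adherens junction cadherin, fell by 0.49 (adjusted p = 0.0435, range 0.0127 to 0.144). That call of Cdh1 was lost without any 1 of the 12 libraries but Primary2 reps 1 and 2 (0.0506 to 0.107), with only the groups compared (0.0684) or with Met1 included (0.144). In the unfolded protein and amino acid response 8 of 15 rose and 1 fell [10 and 1] (median 0.57, adjusted p = 0.0257). The stress transcription factor Atf4 rose by 0.85 (SE 0.17), whereas the cystine transporter Slc7a11 fell by 1.68 (SE 0.23). The unfolded protein response gave 5 higher without Met2 rep 3 or Primary3 rep 3, 4 without Primary2 rep 3 or Primary3 rep 1 and 3 without Met3 rep 2 or Primary2 rep 1. Both lists gave an adjusted p = 0.658 with an estimated correlation, over ranges of 0.000534 to 0.658 (epithelial) and 0.00673 to 0.658 (unfolded protein). Each was also lost without Met2 rep 3 (0.075) or Primary2 rep 1 (0.0646). The epithelial list was lost with fry (0.0594), and the other list with a filter of CPM of at least 1 in 3 libraries (0.0523) or only the groups compared (0.0733).

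**Figure D3:**
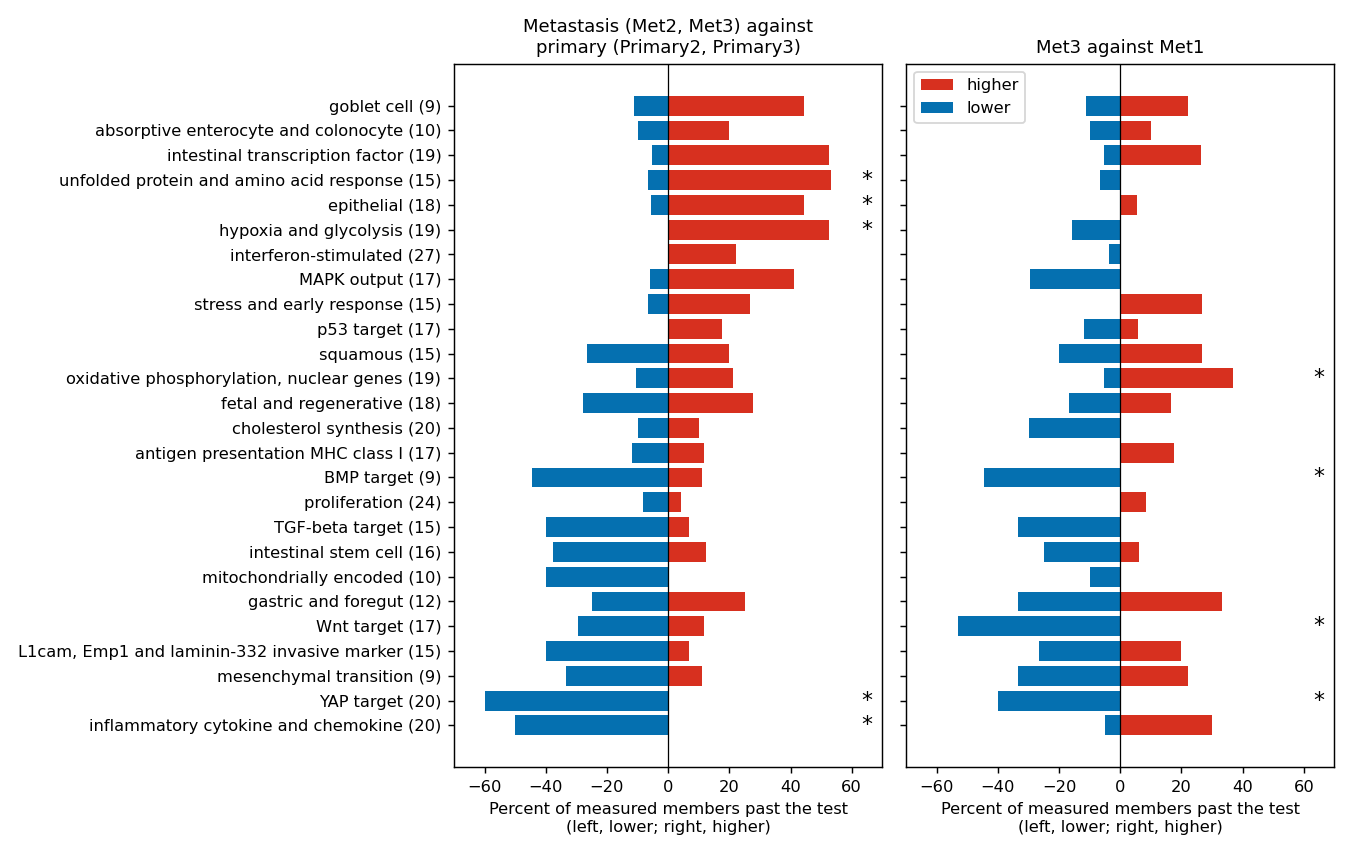
Percent of each list's measured members that were higher (right of 0) or lower (left of 0) in metastasis against primary and in Met3 against Met1, by the edgeR test over all genes. An asterisk marks lists with a camera adjusted p under 0.05.

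Genes of intestinal identity moved in both directions in metastasis against primary without a list passing camera with all libraries and the count filter. Cdx2, the transcription factor that specifies intestine, rose from 18.9 ± 5.13 and 23.5 ± 5.94 CPM in Primary2 and Primary3 to 92.5 ± 19.1 and 80.4 ± 15.7 in Met2 and Met3 (log2 2.03, SE 0.18, adjusted p = 2.7e-05). Of 19 intestinal transcription factors 10 rose and 1, Gata6, fell [10 and 2 adjusted over the list alone] (adjusted p = 0.0906). Goblet cell genes gave 4 higher and 1 lower of 9 [6 and 1] (adjusted p = 0.169). Absorptive genes gave 2 higher and 1 lower of 10 [2 and 1] (adjusted p = 0.526). Stem cell genes gave 2 higher and 6 lower of 16 [2 and 7] (adjusted p = 0.0906), among them Aqp1. Wnt targets gave 2 higher and 5 lower of 17 [2 and 6] (adjusted p = 0.0906). Absorptive genes gave 5 higher and 3 lower of 12 [5 and 3] without Met2 rep 1, and Wnt targets 8 lower. By fry the stem cell (0.000504), goblet (0.0207), Wnt (0.0316) and transcription factor lists (0.0319) passed. With no low-count filter the goblet (0.0162), stem cell (0.0171) and Wnt lists (0.0209) passed, and so did stem cell genes without Met2 rep 2 (0.0413) and Wnt targets without Met2 rep 1 (0.00924). The highest adjusted p of these 4 lists over the alternatives was 0.658.

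Several fetal, invasive and foregut genes fell in the same comparison. Of 18 fetal and regenerative genes 5 rose and 5 fell [5 and 6 adjusted over the list alone] (adjusted p = 0.45, median 0.04, mean -0.60, test downward). The secreted chaperone Clu fell by 4.03 (SE 0.40). Of 15 invasive markers 1 rose and 6 fell [2 and 6] (adjusted p = 0.0891). The integrin subunit Itgb6 fell by 1.85 (SE 0.15), whereas the urokinase receptor Plaur rose by 0.74 (SE 0.14). Gastric and foregut genes gave 3 higher and 3 lower of 12 [3 and 3] (adjusted p = 0.741, median -0.20, mean 0.25, test downward). Squamous genes gave 3 higher and 4 lower of 15 [4 and 4] (adjusted p = 0.908, median 0.15, mean -0.31, test downward). Invasive markers gave 4, gastric genes 5 and squamous genes 5 higher without Met2 rep 1. Without Met3 rep 1 invasive markers gave 3 and squamous genes 2 lower, and without Met3 rep 3 the latter gave 5 higher. By fry the fetal list passed (0.0422, range 0.0422 to 0.995). Invasive markers passed by fry (0.0207), without Met2 rep 2 (0.0271), Met3 rep 2 (0.0247) or Primary3 rep 1 (0.045), with no low-count filter (0.00841), with the replicate block (0.0415) and with the covariate (0.0488, range 0.00841 to 0.658).

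Mesenchymal transition genes gave 1 higher and 3 lower of 9 [1 and 4 adjusted over the list alone] (adjusted p = 0.161). The transcription factor Twist1 rose by 3.73 (SE 0.78), while Cald1 fell by 3.68 (SE 0.52). TGF-beta targets gave 1 higher and 6 lower of 15 [1 and 6] (adjusted p = 0.122). BMP targets gave 1 higher and 4 lower of 9 [1 and 4] (adjusted p = 0.713). MAPK output gave 7 higher and 1 lower of 17 [7 and 2] (adjusted p = 0.172). MHC class I genes gave 2 higher and 2 lower of 17 [2 and 2] (adjusted p = 0.713, median -0.01, mean 0.18, test upward). Interferon-stimulated genes gave 6 higher and 0 lower of 27 [5 and 0] (adjusted p = 0.122), and passed without Primary2 rep 3 (0.0207, range 0.0207 to 0.804). Mesenchymal genes gave 7 lower of 11 and MHC class I 4 higher without Met2 rep 1. MAPK output gave 4 higher without Primary3 rep 2, and BMP targets 2 lower without each of 8 libraries in turn. Interferon-stimulated genes gave 1 without Met3 rep 2, 2 without Primary2 rep 2 and 3 without Primary2 rep 1 or any Primary3 library. With no low-count filter the mesenchymal and TGF-beta lists passed (0.0162 each, the lowest over the alternatives, the highest being 0.658), as they did by fry (0.0316 and 0.0447). The mesenchymal list also passed without Met2 rep 1 (0.0378) or Primary3 rep 2 (0.0338), and TGF-beta targets without Met3 rep 2 (0.0492) or Primary3 rep 1 (0.045).

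Of 24 proliferation genes 1 rose and 2 fell [0 and 0 adjusted over the list alone] (adjusted p = 0.741). Cholesterol synthesis gave 2 higher and 2 lower of 20 [2 and 2] (adjusted p = 0.747). Nuclear genes of oxidative phosphorylation gave 4 higher and 2 lower of 19 [5 and 2] (adjusted p = 0.317). The p53 targets gave 3 higher and 0 lower of 17 [3 and 0] (adjusted p = 0.25). Stress and early response genes gave 4 higher and 1 lower of 15 [5 and 1] (adjusted p = 0.526). Mitochondrially encoded genes gave 0 higher and 4 lower of 10 [0 and 4] (adjusted p = 0.197), among them the complex I subunit mt-Nd5 (-0.49, SE 0.10). Cholesterol synthesis gave 4 higher without Met2 rep 1 or Met3 rep 3, and p53 targets 6 without the former. Stress genes gave 2 higher without Primary2 rep 1 or Primary3 rep 2, and the mitochondrial list 2 lower without Met2 rep 2 or 3, Met3 rep 1 or Primary2 rep 3. By fry the mitochondrial list passed (0.0462, range 0.0462 to 0.66).

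The other 9 lists held fewer than 5 measured genes and were not tested as groups. Both measured Paneth cell genes (Mmp7 and Itln1) and both hepatocyte genes (Alb and Apoa2) were without a call in metastasis against primary, as were the endothelial pair Tie1 and Vwf and the fibroblast gene Fbln1. Tuft cell genes gave 1 lower of 4 (1 adjusted over the list alone), the prostaglandin synthase Ptgs1 (-2.86, SE 0.29, adjusted p = 5.56e-05). MHC class II genes gave 2 lower of 3 (2 lower and 1 higher adjusted over the list alone), among them the invariant chain Cd74 (-2.92, SE 0.57, adjusted p = 0.00249). Of 2 leukocyte genes the receptor Csf1r fell (-4.46, SE 0.69, adjusted p = 0.00068) and the lysosomal protein Cd68 rose (0.97, SE 0.30, adjusted p = 0.0266). The call of Cd68 was lost without Met2 rep 2 (0.0585), Met3 rep 2 (0.0602), Primary2 rep 1 (0.0564) or Primary2 rep 3 (0.058), within a range of 0.00606 to 0.0602. Enteroendocrine and erythroid genes gave 0 measured, with highest values of 4.26 CPM for Isl1 and 1.0 CPM for the globin Hba-a2.

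Within round 2, Met2 against Primary2 (3 against 3 libraries), Bex1 was lower by a ratio of 8060 (2230 to 66500, adjusted p = 0.000129). Tlx1 was at least 225-fold lower (adjusted p = 0.00108) and Tfap2b at least 186-fold lower (adjusted p = 0.00105). Fundc2 rose by 8.70 (SE 1.89, adjusted p = 0.0143), Stk39 by 7.86 (SE 1.40, adjusted p = 0.00592) and the adaptor Pid1, which dampens insulin signalling, by a ratio of 317 (87.3 to 2630, adjusted p = 0.0161). The call of Fundc2 was lost without Primary2 rep 1 (0.0544) or rep 3 (0.0596) and with limma-voom (0.238, range 0.000172 to 0.238). Pid1 was lost without any 1 Primary2 library (0.054 to 0.0647) and with limma-voom (0.263, range 3.3e-06 to 0.263). Stk39 was lost with limma-voom (0.208) and with only the groups compared (0.0567, range 1.27e-06 to 0.208). In all 1768 genes differed, 821 higher and 947 lower, and 1702 of them did not overlap, which selection by p favours. The count was 715 without Primary2 rep 3, 806 without Primary2 rep 1, 923 without Primary2 rep 2 and 1132 without Met2 rep 3. It was 330 with the covariate, 215 with only the groups compared and 2830 with DESeq2.

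Of the lists, YAP targets fell in Met2 against Primary2, 7 of 20 lower [11 adjusted over the list alone] (adjusted p = 7.57e-05), with Ankrd1 at -6.12 (SE 0.95, adjusted p = 0.00321). Cytokines and chemokines gave 6 lower of 20 [8] (adjusted p = 0.00306), with Cxcl5 at -3.91 (SE 0.73, adjusted p = 0.00719). Hypoxia and glycolysis gave 5 higher of 19 [7] (adjusted p = 3.88e-05), and stem cell genes 3 lower of 16 [3] (adjusted p = 0.014). Proliferation gave 2 lower of 24 [2] and mitochondrially encoded genes 4 lower of 10 [6], each with an adjusted p = 0.014, and mt-Nd5 stood at -0.94 (SE 0.14, adjusted p = 0.00263). The unfolded protein response gave 1 higher and 1 lower of 15 [3 and 1] (adjusted p = 0.0292). Invasive markers gave 1 higher and 3 lower of 15 [2 and 5] (adjusted p = 0.0329), with Itgb6 at -1.95 (SE 0.22, adjusted p = 0.000816). Without Met2 rep 1 hypoxia and glycolysis gave 2 higher [1], stem cell genes 5 lower [6] and the unfolded protein response 3 higher [6]. Hypoxia and glycolysis gave 3 without Met2 rep 2 or 3 and 0 without Primary2 rep 1 or 3. YAP targets gave 3 lower without Met2 rep 3 or Primary2 rep 1 and 2 without Primary2 rep 3. Proliferation gave 0 lower without Met2 rep 3 or Primary2 rep 1 and 1 without Primary2 rep 2 or 3. None of these 8 lists passed with an estimated correlation (adjusted p from 0.49 to 0.785), and over all alternatives the 8 lists reached from 1.69e-07 to 0.836.

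Some of these round 2 list calls were lost without 1 library (a smaller fit), and the cause was not tested. Proliferation was lost without Met2 rep 1 (0.116), Met2 rep 3 (0.0729) or Primary2 rep 1 (0.141), within a range of 0.000768 to 0.836. The mitochondrial list was lost without Met2 rep 3 (0.062, range 0.00118 to 0.714). The unfolded protein list was lost without Met2 rep 3 (0.17) or Primary2 rep 1 (0.141, range 0.00605 to 0.836), and invasive markers without Met2 rep 1 (0.181) or Primary2 rep 3 (0.0528, range 0.00394 to 0.785). The ribosomal covariate ended the calls of proliferation (0.836), the unfolded protein response (0.836), hypoxia and glycolysis (0.371) and the mitochondrial list (0.277). Fry ended the calls of proliferation (0.264), the unfolded protein response (0.198), hypoxia and glycolysis (0.0717), invasive markers (0.0717) and cytokines (0.0672).

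Within round 3, Met3 against Primary3 (3 against 3 libraries), Bex1 was at least 6250-fold lower (adjusted p = 7.54e-05), Tlx1 at least 565-fold lower (adjusted p = 0.000336) and Ppic lower by a ratio of 21000 (5820 to 174000, adjusted p = 0.00114). Ryr3 was at least 258-fold higher (adjusted p = 0.00244). Ffar4 was higher by a ratio of 2130 (381 to 84000, adjusted p = 0.00217) and Stk39 by 758 (136 to 30000, adjusted p = 0.00446). With limma-voom the adjusted p of Ffar4 was 0.0679 (range 1.77e-09 to 0.0679) and that of Stk39 0.201 (range 2.3e-06 to 0.201). In all 2850 genes differed, 1212 higher and 1638 lower, 2819 of them without overlap, which selection by p favours. The count was 1372 without Primary3 rep 3, 1415 without Met3 rep 1, 1614 without Primary3 rep 2, 1785 without Met3 rep 2 and 1746 with the covariate.

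In Met3 against Primary3, YAP targets fell, 9 of 20 lower [10 adjusted over the list alone] (adjusted p = 0.00495), with Ankrd1 at -7.90 (SE 1.03, adjusted p = 0.000738). Cytokines and chemokines gave 7 lower of 20 [7 lower and 1 higher] (adjusted p = 0.02), with Csf2 at -6.18 (SE 0.89, adjusted p = 0.00134). Epithelial genes gave 6 higher of 18 [7] (adjusted p = 0.00495), with Cldn3 at 1.0 (SE 0.17, adjusted p = 0.00253). Intestinal transcription factors gave 9 higher and 1 lower of 19 [9 and 1] (adjusted p = 0.0396), with Cdx2 at 1.78 (SE 0.26, adjusted p = 0.00134) and the pioneer factor Foxa1 at 1.10 (SE 0.14, adjusted p = 0.000738). YAP targets gave 5 lower without Met3 rep 1 or Primary3 rep 3, and epithelial genes 3 higher without any 1 Primary3 library. Each of these 4 lists gave an adjusted p = 0.713 with an estimated correlation, the highest over the alternatives, the lowest running from 4.1e-05 to 0.00697. The cytokine call was lost without Met3 rep 3 (0.11). The transcription factor call was lost without Met3 rep 1 (0.0715), with only the groups compared (0.118), with the filter of CPM of at least 1 (0.0519) and with fry (0.0549). Fry also ended the epithelial call (0.072).

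Across 14925 genes the log2 changes of the 2 rounds correlated with a Pearson r of 0.614 and a Spearman rho of 0.547, from comparisons that share no library. Of the genes that passed the test in both, 413 were higher in both (66.7 expected) and 556 lower in both (104 expected), while 2 went opposite ways (167 expected). Of the genes past the test in round 2, 93.4% had the same sign in round 3.

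**Figure D4:**
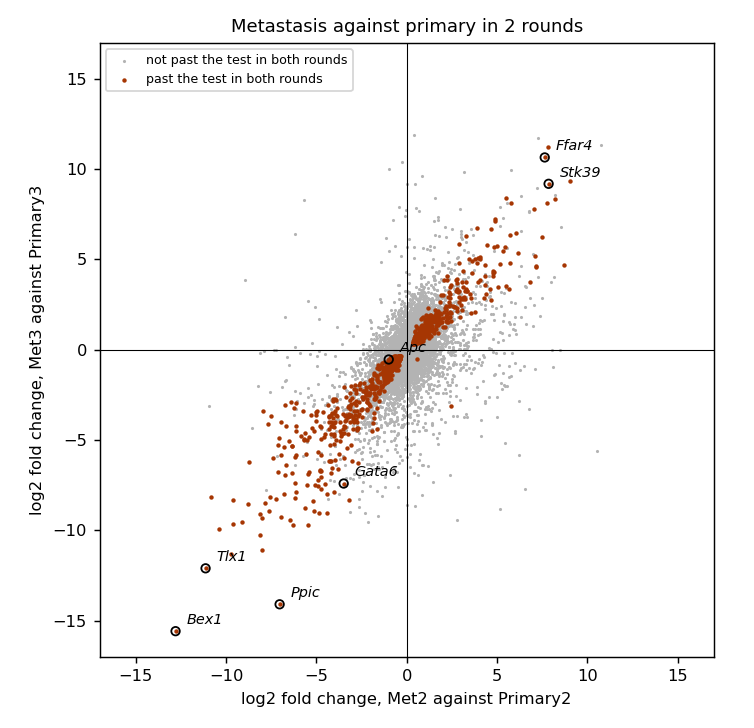
Log2 fold change of Met2 against Primary2 (horizontal) and of Met3 against Primary3 (vertical), 1 point per gene, with genes past the test in both rounds in colour. The Pearson r across genes was 0.614.

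The difference between rounds was tested directly, as Met3 against Primary3 minus Met2 against Primary2. The complex I subunit mt-Nd5 had the smallest p among list members, at 0.91 (SE 0.19, adjusted p = 0.261). The replication and mitosis genes Cenpe (1.05, SE 0.36, adjusted p = 0.31) and Top2a (0.59, SE 0.25, adjusted p = 0.37) leaned the same way. By edgeR 0 genes passed (1817 at an unadjusted p under 0.05), by limma-voom 0 and by DESeq2 224. Without Met2 rep 2 the count was 17 and without Met2 rep 1 it was 1.

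Met3 against Met1 compares the last with the first round of metastasis-derived organoids (3 against 3 libraries). Trp53i11, a p53-induced membrane protein, rose from 0.0639 to 67.8 ± 18.1 CPM (log2 9.87, SE 1.87, adjusted p = 0.00396). Ryr3 was higher by a ratio of 993 (178 to 39200, adjusted p = 0.00268), the skin cornification gene Lce3b by 775 (139 to 30700, adjusted p = 0.00126) and Nat8l, which makes N-acetylaspartate, by 361 (123 to 1750, adjusted p = 0.00179). Muc5ac, the secreted mucin of stomach and airway, rose by 8.10 (SE 2.33, adjusted p = 0.0258) to 38.0 ± 7.30 CPM. The prolactin-family gene Prl2c2 was at least 117-fold higher (adjusted p = 0.0173), the processed pseudogene AC127331.9 at least 93.1-fold (adjusted p = 0.00472) and the pseudogene Rpl19-ps11 at least 81.7-fold (adjusted p = 0.0376). The pseudogene Obox4-ps27 had a ratio of 469 (83.8 to 18600, adjusted p = 0.029). These last 4 have close copies elsewhere in the genome, so their short reads are hard to place.

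The largest falls in Met3 against Met1 were in Bex1, at least 2030-fold lower (adjusted p = 0.000211), and in Irx4, a homeobox factor of the heart ventricle, at least 354-fold lower (adjusted p = 0.0151). The secreted Wnt inhibitors Wif1 and Dkk3 were at least 269-fold (adjusted p = 0.0158) and at least 71.5-fold lower (adjusted p = 0.017). The lipid carrier Pctp (adjusted p = 0.0025) and the secreted Igfbp7, which binds growth factors (adjusted p = 0.00334), were each at least 182-fold lower. Tnik, a kinase of the Wnt transcription complex, fell from 28.9 ± 12.1 CPM by a ratio of 1570 (281 to 62000, adjusted p = 0.00316). The antimicrobial phospholipase Pla2g2a fell by 9.20 (SE 1.64, adjusted p = 0.00323), and the RNA-binding protein Rbms3 by a ratio of 556 (99.4 to 22000, adjusted p = 0.0115).

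In Met3 against Met1, 3499 genes differed, 1734 higher and 1765 lower, 3413 of them without overlap, which selection by p favours. The count was 1988 without Met1 rep 2 and 2161 without Met3 rep 1. Muc5ac was lost without any 1 Met1 library (0.0719 to 0.0912), with limma-voom (0.156) and in a trend over rounds (0.297, range 0.000226 to 0.297). Prl2c2 was lost without Met1 rep 2 (0.0523), with limma-voom (0.0635) and in the trend (0.203, range 7.29e-06 to 0.203). Rpl19-ps11 was lost without each of the 6 libraries in turn (0.0597 to 0.0954), with limma-voom (0.126) and in the trend (0.147, range 0.000487 to 0.147). Obox4-ps27 was lost without Met1 reps 1 (0.0837), 2 (0.0913) or 3 (0.086) or Met3 rep 1 (0.0662, range 0.00475 to 0.0913). Limma-voom ended the calls of Trp53i11 (0.153, range 2.64e-07 to 0.153), Irx4 (0.0588, range 2.74e-05 to 0.0588) and Wif1 (0.0673), and the trend those of Trp53i11 (0.0538) and Wif1 (0.105, range 1.03e-05 to 0.105).

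Of 17 Wnt target genes 9 fell and 0 rose in Met3 against Met1 [9 and 0 adjusted over the list alone] (median -1.56, adjusted p = 0.000731). The transcription factor Tcf7 fell by 1.62 (SE 0.22) and the receptor ligase Znrf3 by 1.56 (SE 0.26). Of 9 BMP targets 4 fell [6] (median -2.61, adjusted p = 0.0477), among them the transcription factor Atoh8 (-4.67, SE 1.05). Of 20 YAP targets 8 fell [8] (median -0.85, adjusted p = 0.0477), among them Ccn2 (-4.54, SE 0.71). Of 19 nuclear genes of oxidative phosphorylation 7 rose and 1 fell [9 and 1] (median 0.30, adjusted p = 0.0477). The complex I subunit Ndufa1 rose by 0.86 (SE 0.15), whereas Uqcrc1 of complex III fell by 0.73 (adjusted p = 0.00966). Without Met3 rep 1 Wnt targets gave 5 lower, BMP targets 1, YAP targets 2 and oxidative phosphorylation 4 higher. BMP targets also gave 1 without Met1 rep 3 or Met3 rep 2, and oxidative phosphorylation 4 without Met1 rep 1 or 2. YAP targets gave 5 without Met1 rep 2 or Met3 rep 2, 4 without Met1 rep 3 and 3 without Met3 rep 3. All 4 lists gave an adjusted p = 0.928 with an estimated correlation, their highest over the alternatives.

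The lowest adjusted p over the alternatives was 1.51e-05 for Wnt targets, 0.00335 for BMP targets, 0.00205 for YAP targets and 0.0173 for oxidative phosphorylation. The BMP call, which includes Atoh8, was lost without Met1 rep 3 (0.108) or Met3 rep 1 (0.0684), with the filter of CPM of at least 1 (0.0749) and with fry (0.105). The YAP call, which includes Ccn2, was lost without Met1 rep 2 (0.0909), Met1 rep 3 (0.148) or Met3 rep 1 (0.114), with that filter (0.0749) and with fry (0.0596). The oxidative phosphorylation call, which includes Ndufa1, was lost without Met1 rep 1 (0.0818) or Met3 rep 1 (0.0684) and with that filter (0.051).

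The other tested lists gave adjusted p from 0.0555 (cholesterol synthesis, 0 higher and 6 lower of 20, 0 and 7 adjusted over the list alone) to 0.997 (absorptive genes) in Met3 against Met1. Hypoxia genes gave 0 higher and 3 lower of 19 (0 and 3 adjusted over the list alone), and Car9, the hypoxia-induced carbonic anhydrase, fell from 145 ± 87.4 to 3.55 CPM (-5.34, SE 0.90, adjusted p = 0.00284). Of 20 cytokines and chemokines 6 rose and 1 fell (7 and 1 adjusted over the list alone), with the neutrophil chemokine Cxcl1 up by 3.25 (SE 0.52, adjusted p = 0.00247). Cholesterol synthesis gave 3 lower without Met3 rep 1, and cytokines 3 higher without Met1 rep 2 or 3 or Met3 rep 1 or 2. Median, mean and test differed in sign for the fetal list (0.37, -0.55, upward), absorptive genes (0.51, -0.07, downward) and intestinal transcription factors (-0.04, -0.01, upward).

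Of these lists without a call in Met3 against Met1, 9 passed in some alternative, and with an estimated correlation the adjusted p of each was 0.928, its highest. With the covariate hypoxia genes (0.00449), TGF-beta targets and proliferation (0.0135 each), cholesterol synthesis (0.0295) and the unfolded protein response (0.0469) passed. With no low-count filter cholesterol synthesis (0.00335), hypoxia genes and TGF-beta targets (0.0173 each) passed, and with only the groups compared cholesterol synthesis, hypoxia and stem cell genes (0.0434 each). The replicate block gave 0.047 for cholesterol synthesis and 0.0476 for TGF-beta targets. Without Met3 rep 2 TGF-beta targets (0.0434), cholesterol synthesis (0.0442) and hypoxia genes (0.0467) passed. Without Met1 rep 1 hypoxia genes, TGF-beta targets and MHC class I (0.0497 each) passed, and without Met3 rep 3 cytokines (0.00812) and stress genes (0.0333).

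Lists with fewer than 5 measured genes also held single calls in Met3 against Met1. The hepatocyte product Alb was lower by a ratio of 167 (29.5 to 6620, 184 against 1 counts, adjusted p = 0.0119), a call lost without Met3 rep 1 (0.0519, range 0.00422 to 0.0519). Of the endothelial genes, the clotting factor Vwf fell by 4.97 (SE 0.88, adjusted p = 0.00312), with 46.1 CPM in Met1 rep 2, and the receptor Tie1 rose by 3.98 (SE 0.78, adjusted p = 0.00458). Limma-voom ended the call of Vwf (0.0853, range 2.79e-08 to 0.0853). The fibroblast gene Fbln1 rose by 3.06 (SE 0.83, adjusted p = 0.0204), a call lost without Met1 reps 2 (0.079) or 3 (0.0723) or Met3 reps 1 (0.0627) or 3 (0.0542, range 0.00733 to 0.079). Markers of other cell types summed to 77.8 CPM in Met1 rep 2, the highest of the 15 libraries.

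In Met2 against Met1 (3 against 3 libraries) Bex1 was lower by a ratio of 2430 (674 to 20100, adjusted p = 0.000493), Ggta1 by 726 (130 to 28700, adjusted p = 0.00049) and the skin phospholipase Pla2g2f at least 137-fold (adjusted p = 0.0066). Cryba4, a lens crystallin, rose by 8.15 (SE 1.49, adjusted p = 0.00773), Lce3b by a ratio of 265 (46.9 to 10500, adjusted p = 0.00562) and AC127331.9 at least 51.9-fold (adjusted p = 0.0129). The ribosomal covariate ended the calls of AC127331.9 (0.132), Cryba4 (0.104) and Lce3b (0.102), and limma-voom did so too (0.07, 0.138 and 0.0737). With only the groups compared the adjusted p was 0.0864 for Cryba4, 0.0633 for Lce3b, 0.0514 for Ggta1 and 0.0659 for Pla2g2f. Over all alternatives the ranges were 7.03e-06 to 0.132 (AC127331.9), 2.32e-10 to 0.138 (Cryba4), 1.83e-06 to 0.102 (Lce3b), 7.15e-11 to 0.0514 (Ggta1) and 1.19e-07 to 0.0659 (Pla2g2f). In all 2428 genes differed, 1298 higher and 1130 lower, 2305 of them without overlap, which selection by p favours. The count was 573 without Met1 rep 2, 1520 without Met1 rep 3, 159 with the covariate and 14 with only the groups compared.

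Stem cell genes fell in Met2 against Met1, 5 of 16 lower [5 adjusted over the list alone] (adjusted p = 0.0033). Wnt targets gave 6 lower of 17 [6 lower and 1 higher] (adjusted p = 0.0033) and YAP targets 4 lower of 20 [5] (adjusted p = 0.0127), with Ccn2 at -3.53 (SE 0.68, adjusted p = 0.00944). With an adjusted p = 0.0415 each, invasive markers gave 2 higher and 5 lower of 15 [3 and 7] and TGF-beta targets 3 lower of 15 [4 lower and 1 higher]. So did oxidative phosphorylation, 5 higher of 19 [8], and the unfolded protein response, 2 lower of 15 [1], with Slc7a11 at -1.64 (SE 0.33, adjusted p = 0.0102). Wnt targets gave 11 lower [12] without Met2 rep 1. Without Met1 rep 2 Wnt targets gave 3 lower, YAP targets 2, stem cell genes, TGF-beta targets and invasive markers 1 each and oxidative phosphorylation 1 higher. Without Met1 rep 1 stem cell genes gave 3 lower and oxidative phosphorylation 2 higher, and without Met2 rep 2 the latter gave 3. Invasive markers gave 3 lower without Met1 rep 3, 2 without Met2 rep 3 and 0 higher without any 1 library but Met2 rep 1, and the unfolded protein response 1 lower without any but Met2 rep 3. With an estimated correlation the adjusted p was 0.193 for stem cell genes and 0.87 for the other 6 lists. With only the groups compared the calls of Ccn2 (0.0819, range 3.14e-07 to 0.0819) and Slc7a11 (0.0872, range 2.86e-05 to 0.0872) were lost.

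Of these lists, invasive markers were lost without Met1 rep 2 (0.0608), Met1 rep 3 (0.0755) or Met2 rep 1 (0.32). TGF-beta targets were lost without any 1 library but Met1 rep 1 (0.0522 to 0.154). YAP targets were lost without Met1 rep 3 (0.113) or Met2 rep 3 (0.0533), and oxidative phosphorylation without Met1 rep 1 (0.116) or Met2 reps 1 (0.0812) or 2 (0.0522). The unfolded protein response, with Slc7a11, was lost without Met1 rep 2 (0.154) or Met2 reps 1 (0.115) or 2 (0.137). Fry ended the calls of all 5 (0.068 to 0.165), and the ribosomal covariate that of oxidative phosphorylation (0.287). In each case the highest adjusted p over the alternatives was 0.87, and the lowest were 0.00444, 0.000785, 0.000217, 0.0189 and 0.000118 in that order.

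In Met3 against Met2 (3 against 3 libraries) Txnip, which restrains glucose uptake, rose from 78.4 ± 8.58 to 279 ± 145 CPM (log2 1.83, SE 0.31, adjusted p = 0.0386). The phosphatase regulator Ppp1r10 rose by 1.23 (SE 0.22, adjusted p = 0.0404). Pctp was at least 118-fold lower (adjusted p = 0.0386). The glutamine transporter Slc38a1 fell by 4.89 (SE 0.88) and the zinc-finger gene Zfp429 by 2.80 (SE 0.51), each with an adjusted p = 0.0433. In all 41 genes differed, 8 higher and 33 lower, each of the 41 without overlap, which selection by p favours. The count was 0 by edgeR without Met2 rep 1, 2 without Met3 rep 1 or 2, 10 without Met3 rep 3, 68 without Met2 rep 3 and 203 without Met2 rep 2. It was 68 with upper-quartile factors, 85 with no low-count filter, 588 with DESeq2 and 4 with limma-voom, and by edgeR 0 with the replicate block, the covariate or only the groups compared. Without Met2 rep 1 or Met3 rep 1 or 2 all 5 named genes lost their calls (0.0583 to 0.178). Ppp1r10 (0.0583), Pctp (0.0705), Slc38a1 (0.0989) and Zfp429 (0.107) were also lost without Met3 rep 3, and Txnip and Zfp429 without Met2 rep 3 (0.0554 each). The replicate block, the ribosomal covariate and limma-voom ended all 5 calls. With only the groups compared 4 of them stood at 0.591, the highest over the alternatives, and Pctp reached 0.296 with limma-voom, the lowest for the 5 running from 2.11e-08 to 4.82e-05.

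Of the lists, 5 passed in Met3 against Met2, each with 0 members past the edgeR test. Epithelial genes (median 0.28), proliferation genes (0.23) and stress genes (0.72) leaned upward with an adjusted p = 0.00299 each, intestinal transcription factors (0.43) with an adjusted p = 0.0208. Cholesterol synthesis leaned downward (-0.30, adjusted p = 0.00924). Foxa1 stood at 0.64 (adjusted p = 0.0792), the early response factor Ier2 at 0.57 (adjusted p = 0.082) and Pmvk at -0.74 (adjusted p = 0.082). With an estimated correlation all 5 lists gave an adjusted p = 0.748, the highest over the alternatives, the lowest running from 4.66e-06 to 0.000383. Without Met2 rep 1 the epithelial and transcription factor lists (0.315 each) and proliferation (0.0895) were lost. Proliferation (0.0664) and cholesterol synthesis (0.273) were lost without Met2 rep 3, and stress genes without Met3 rep 2 (0.0618). The covariate ended the calls of proliferation (0.282) and cholesterol synthesis (0.167), and fry those of all 5 (0.366 to 0.52).

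In Primary3 against Primary2 (3 against 3 libraries) the mitochondrial gene mt-Nd4 stood at -0.48 (SE 0.13, adjusted p = 0.62), the keratin Krt15 at 2.87 (adjusted p = 0.62) and Cxcl1 at 1.32 (adjusted p = 0.638). By edgeR 0 genes passed (1063 at an unadjusted p under 0.05), by DESeq2 43 and by limma-voom 1, and without Primary2 rep 3 edgeR gave 2. As groups, proliferation genes (median -0.29, adjusted p = 6.62e-05) and mitochondrially encoded genes (-0.38, adjusted p = 0.000269) leaned downward. Stress (0.49, adjusted p = 0.0112), squamous (0.34, adjusted p = 0.0166), fetal (0.23, adjusted p = 0.0229), interferon-stimulated (0.35, adjusted p = 0.0278) and cytokine genes (0.36, adjusted p = 0.0309) leaned upward. With an estimated correlation the adjusted p was 0.871 for the interferon list and 0.838 for the other 6.

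Of these 7 lists in the primaries, 6 were lost without 1 library. Proliferation, which includes Top2a and Bub1, was lost without Primary2 rep 1 (0.0596), and stress genes without Primary2 rep 1 (0.113) or Primary3 rep 3 (0.054). Fetal genes were lost without Primary2 reps 1 (0.18) or 3 (0.0692) or Primary3 rep 3 (0.0931). Squamous genes such as Krt15 were lost without any 1 of the 6 libraries (0.0592 to 0.142). Interferon genes were lost without Primary2 reps 1 (0.873) or 2 (0.0813) or Primary3 reps 2 (0.0698) or 3 (0.101). Cytokines such as Cxcl1 were lost without any 1 library but Primary2 rep 3 (0.0534 to 0.398). The squamous call ended with no low-count filter (0.0621) and the interferon call with the filter of CPM of at least 1 (0.0538). Fry ended all 7 calls (0.247 to 0.781), and the covariate all but that of the mitochondrially encoded genes such as mt-Nd4. Over all alternatives the 7 lists reached from 1.33e-10 to 0.873.

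Gata6, Apc and Ppic lie on chromosome 18, whose 288 tested genes had a median log2 change of -0.43 in metastasis against primary. Relative to each library's median gene, chromosome 18 lay between -0.193 and -0.0853 (log2) in the 9 metastasis libraries, Met1 included, and between 0.153 and 0.35 in the 6 primary libraries. Such medians parted all 9 from all 6 libraries for 8 of 20 chromosomes. Met2 rep 1 held the largest shift of any library, 0.66 on chromosome 5.

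**Figure D5:**
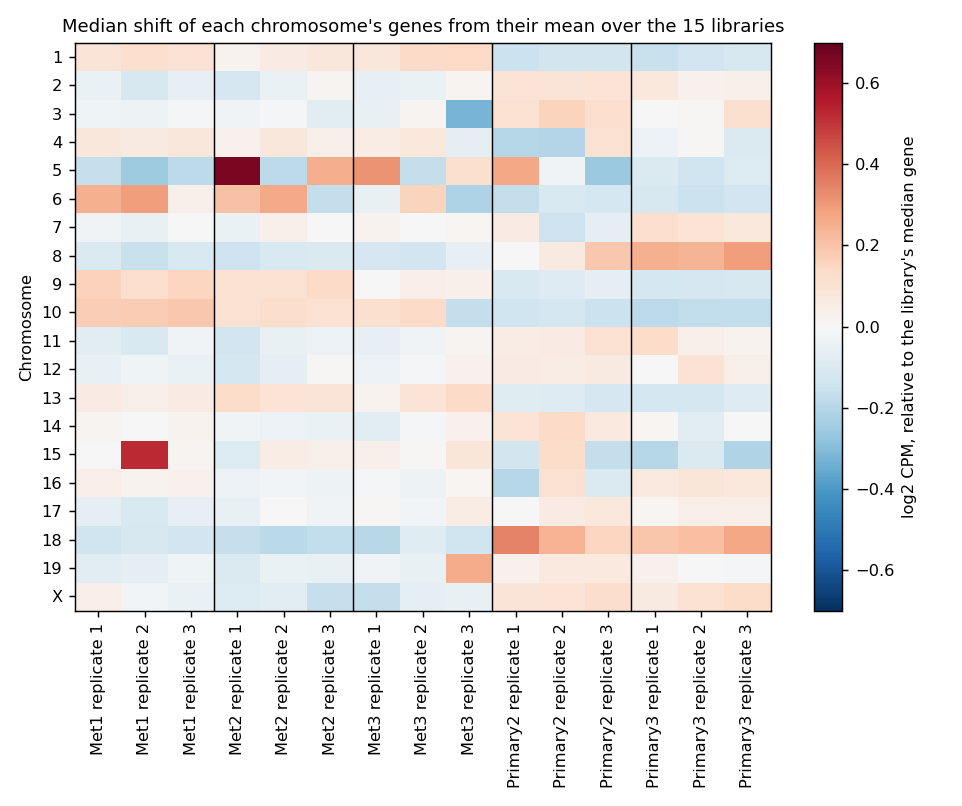
Median shift of each chromosome's genes (log2 CPM relative to the median gene of the library) in the 15 libraries, as a heat map. Chromosome 18 was lower in the 9 metastasis than in the 6 primary libraries.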

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

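The test for more ribosomal RNA in Met2 rep 1, the test of whole-chromosome dosage over the changed genes, the ribosomal covariate and the direction test over both rounds were chosen only after the results were seen. In the direct test of round 3 against round 2, the difference of metastasis and primary organoids itself differed between rounds for 6 gene lists. Proliferation genes (median log2 difference 0.49, adjusted p = 8.46e-07), such as the mitotic kinesin Cenpe and the topoisomerase Top2a, and mitochondrially encoded genes (0.60, adjusted p = 0.0027), such as mt-Nd5 and mt-Nd4, were relatively higher in round 3. So were epithelial genes (0.21, adjusted p = 0.0234), such as Cldn3, and MHC class I genes (0.43, adjusted p = 0.0234), such as the peptide-loading protein Tapbp. Cholesterol synthesis genes (-0.29, adjusted p = 0.0197), such as Pmvk, and hypoxia and glycolysis genes (-0.33, adjusted p = 0.048), such as the mitophagy receptor Bnip3, were relatively lower. Over all genes 0 members passed the edgeR test, DESeq2 called 224 genes in all and limma-voom 0. With an estimated correlation between genes the adjusted p was 0.78 for hypoxia and glycolysis and 0.744 for the other 5 lists, the highest of each list's alternatives. The lowest ran from 1.6e-11 (proliferation) to 0.00365 (MHC class I).

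Only the calls of proliferation and of the mitochondrial genes were kept whichever library was left out. The epithelial call, with Cldn3, was lost without Met2 rep 1 (0.573), Met3 rep 2 (0.0786), Primary2 reps 2 (0.0617) or 3 (0.09) or Primary3 rep 1 (0.0896). MHC class I was lost without Met2 reps 1 (0.0525) or 3 (0.0966), Met3 rep 3 (0.0501), Primary2 rep 3 (0.0992) or Primary3 rep 1 (0.107), and with no low-count filter (0.0511). Hypoxia and glycolysis was lost without Met2 reps 1 (0.0986) or 3 (0.107), Met3 rep 3 (0.199), Primary2 reps 1 (0.305) or 3 (0.0992) or Primary3 reps 2 (0.36) or 3 (0.149), with median-ratio factors (0.0505) and with the filter of CPM of at least 1 (0.0516). Fry ended all 6 calls (0.182 to 0.622). Cholesterol synthesis was lost without Met2 rep 3 (0.211), Met3 rep 3 (0.0547) or Primary2 rep 1 (0.151). Among lists without a call, fetal genes passed without Met2 rep 1 (0.000105), Met3 rep 2 (0.0281) or Primary2 rep 2 (0.0466, range 0.000105 to 0.887).

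The share of ribosomal RNA differed between metastasis and primary organoids by 2.9 percentage points in round 2 and by -1.95 in round 3, so it runs along with the difference between rounds. With that share as a covariate the median of the proliferation list, with Top2a, went from 0.49 to -0.02 (adjusted p = 0.727) and that of the mitochondrial list from 0.60 to 0.29 (adjusted p = 0.396). MHC class I went from 0.43 to 0.15 (0.2) and cholesterol synthesis from -0.29 to -0.12 (0.372), while the epithelial list went from 0.21 to 0.67 (1.63e-05) and hypoxia and glycolysis changed sign, from -0.33 to 0.42 (0.0107). The covariate runs along with the contrast, so whether ribosomal RNA or the rounds account for the differences stays open. No biological explanation was tested, since the groups give none beyond the round itself.

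Met2 rep 1 lay apart from the other Met2 libraries. A wrong label of a library from another group of the series would place it among that group, but its mean correlation (0.9061 with Met1, 0.9005 with Met2 and less with the others) reached the lowest correlation within 0 of the other groups. Hepatocytes, fibroblasts, endothelial or blood cells would raise their markers. The 55 markers summed to 19.5 CPM (other 14 libraries 13.4 to 77.8), led by Cd68 at 8.51 CPM. Its ribosomal share of 6.33% lay between the 6.24% and 7.52% of the other Met2 libraries. A line with its own history stays open, of which its shift of 0.66 on chromosome 5 may be a mark. So do cells of other types and a sample from outside the series, and no biological explanation was tested.

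A difference in ribosomal RNA carried over was weighed for the 4537 genes that differed between metastasis and primary organoids. With the share as a covariate 4237 genes differed, 4086 of the 4537 among them, and the slope of new on old log2 changes was 1.01. That slope was largely set in advance, since the share differences of the rounds nearly cancel (mean 0.477 percentage points), so it says nothing. As these have opposite signs, genes that followed the share should change in opposite directions, but of the 971 genes called in both rounds only 2 did (0.206%), so it is an unlikely cause for those. For the other genes it stays open, and with the covariate the counts went from 1768 to 330 in round 2 and from 2850 to 1746 in round 3. A gene's chromosome explained 0.029 of the variance of the log2 changes. Large changes dominate that, so whole-chromosome dosage stays open for small ones. Bex1, Tlx1 and Cdx2 changed by far more than any chromosome. The difference in tissue of origin, and the separate history of the lines, stay open as untested biological explanations.

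With labels exchanged, only the real one of 100 drawn splits gave as many genes for metastasis against primary (4537, others at most 1686). Chance assignment of labels can thus be excluded for this count. For the difference between rounds the real count was 0, which any split reaches (100 of 100), so this test says nothing. Other splits gave 2289, 1686 and 1 genes and the rest 0. Exchanging all labels of 1 round turns this contrast into metastasis against primary (1686 genes there too), so near exchanges can recover it. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. Real counts and the highest of the other splits were 1768 and 1 (Met2 against Primary2), 2850 and 0 (Met3 against Primary3), 3499 and 0 (Met3 against Met1), 2428 and 1 (Met2 against Met1) and 41 and 3 (Met3 against Met2), so that 1 split, the real one, gave as many genes. For Primary3 against Primary2 they were 0 and 0 in 10 splits, which says nothing either.

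Gata6 near 0 and Gata4 raised in Met2 and Met3 could in principle reflect reads shared between the paralogs, but 0 of 6468 stretches of 31 bases in Gata6 transcripts occur in Gata4 transcripts, against 305 shared between transcripts of Gata6 itself. Deletion of a wide region around Gata6 would remove its neighbours, but the 10 tested genes within 1 Mb had a median log2 change of -0.505, and Abhd3 rose by 1.39 (adjusted p = 0.0282). Among these neighbours Greb1l fell furthest, by 2.4 (adjusted p = 0.00424), followed by Tmem241 (-0.89) and Mib1 (-0.86), so a smaller change around some of them is not excluded. A deletion of Gata6 alone or of a part of the region, silencing of the gene, and the outgrowth of cells with little Gata6 stay open as untested explanations.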

How the results depend on the processing

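The ribosomal covariate and the counts of list members without 1 library were chosen only after the data were seen. Over all alternatives 7348 gene results kept direction and side of the threshold, 599 no longer passed, 80 newly passed and 21 changed sign. For the tested lists of the 2 main comparisons and the called lists of the others, 1243 list results kept both, 189 no longer passed, 48 newly passed and 47 changed direction. For lists without a call in the other comparisons 1671 results kept both, 95 newly passed and 139 changed direction, 3 of them past the threshold with the covariate. Of counts 97 stayed within 1.5 times the reported value and 37 did not, and the 4 correlations between comparisons moved little (0.649 with the stricter filter and 0.614 with median-ratio factors for the 2 rounds).

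The count for Met3 against Met2 was 68 with upper-quartile factors, 85 with no low-count filter, 588 with DESeq2, 4 with limma-voom and, by edgeR, 0 with the replicate block, 0 with the ribosomal covariate and 0 with only the groups compared, whose fit rests on 6 libraries. With the covariate it was 330 for Met2 against Primary2, 1746 for Met3 against Primary3 and 159 for Met2 against Met1. With only the groups compared it was 215 for Met2 against Primary2 and 14 for Met2 against Met1. DESeq2 gave 2830 for Met2 against Primary2, 224 for the difference between rounds and 43 for Primary3 against Primary2, where limma-voom gave 1. Why these counts moved was not tested.

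Leaving out 1 library gave 3656 to 5265 genes for metastasis against primary, 715 to 2150 for Met2 against Primary2, 1372 to 2319 for Met3 against Primary3 and 0 to 17 for the difference between rounds. It gave 1988 to 2702 for Met3 against Met1, 573 to 2527 for Met2 against Met1, 0 to 203 for Met3 against Met2 and 0 to 2 for Primary3 against Primary2. Each fit holds 1 library fewer, and the cause was not tested.

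Of genes followed in the alternatives none past the edgeR test changed sign, and the genes named next had not passed. With the covariate Trp53, Aurka and Kif11 stood at -0.14, -0.023 and -0.15 in Met3 against Met2. Avil stood at -0.048 in metastasis against primary and Apoa2 at 0.10 in Met3 against Met1. In the difference between rounds Adm stood at 1.88, Pfkfb3 at 0.22, Vegfa at 1.56 and Kif11 at -0.070. List calls that changed sign with the covariate gave adjusted p of 0.836 (proliferation, Met2 against Primary2), 0.727 (proliferation, between rounds), 0.282 (proliferation, Met3 against Met2) and 0.0107 (hypoxia and glycolysis, between rounds). Limma-voom put Dclk1 at -0.84 in Met3 against Met1. With Met1 included Alb stood at 0.23 and Mmp7 at 0.29. The cause was not tested.

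The lists without a call in the 2 main comparisons that changed direction did not pass there. In metastasis against primary the adjusted p was 0.972 by fry for BMP targets, 0.998 with no low-count filter for MHC class I and 0.886 with the covariate for proliferation. In Met3 against Met1 it was 0.878 by fry for gastric genes, and 0.834 with no low-count filter and 0.986 with the covariate for intestinal transcription factors. For absorptive genes it was 0.834 with CPM of at least 1, 0.649 with no low-count filter, 0.99 with the replicate block, 0.926 with only the groups compared and 0.994 by fry. Leaving out 1 library gave, in metastasis against primary, 0.217 to 0.916 for BMP targets, 0.363 to 0.947 for MHC class I, 0.363 to 0.99 for cholesterol synthesis, 0.707 to 0.9 for gastric genes, 0.385 to 0.99 for proliferation and 0.494 to 0.99 for squamous genes. In Met3 against Met1 it gave 0.528 to 0.971 (absorptive), 0.57 to 0.971 (fetal), 0.803 to 0.996 (gastric), 0.627 to 0.95 (goblet), 0.391 to 0.985 (interferon), 0.617 to 0.971 (transcription factors) and 0.382 to 0.873 (mitochondrial). The cause was not tested.

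In metastasis against primary, leaving out 1 library moved Alb between -3.06 and 0.55, Apoa2 between -0.87 and 0.12 and Avil between -0.13 and 0.28. In Met3 against Met1 it moved Csf1r between -1.23 and 0.23, Dclk1 between -2.38 and 1.2 and Ptgs1 between -0.12 and 0.97. Smoc2 moved between -0.85 and 2.96 (Met2 against Primary2) and Trp53 between -0.043 and 0.23 (Primary3 against Primary2).

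Whether replicate numbers pair the libraries stays open. Over 30 pairs of the same number correlations ran from -0.126 to 0.268 (median 0.0076). Of 15 libraries 9 matched best with their own number. DESeq2 gave no adjusted p for Dach1 (metastasis against primary) and Obox4-ps27 (Met3 against Met1). Genes near the floor, such as Gata6 in Met3 against Met2, were removed by the filter in fits of only the groups compared. Depth limits what Met2 and Met3 show for Gata6, where some libraries held 0 counts and 3 equal 0.154 to 0.201 unscaled CPM.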

Other observations

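The test of chromosome 18 between Met1 and Met3 and the list tests without Met2 rep 1 were chosen only after the results were seen. Met2 rep 1 had a profile of its own. Hnf4a, a nuclear receptor that maintains intestinal epithelium, held 0 counts there against 4.61 to 94 CPM in the other 14 libraries. The intestinal lectin Lgals4 stood at 9.52 CPM (others 214 to 2250) and the alarmin Il33 at 5.5 (others 68.8 to 520). In return the sensory neuropeptide gene Calcb stood at 83.2 CPM (others 0.629 to 5.22) and Sox2, a foregut and stem cell transcription factor that the count filter removed from the tests, at 136 CPM, where the next highest library, Met1 rep 1, held 8.17. Of the tested genes, 11 lay at least 4-fold above and 75 at least 4-fold below every other library. Met1 rep 2, the next by genes below, gave 5 and 43.

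Without Met2 rep 1, Wnt targets (median -0.90) and mesenchymal transition genes (-3.79) also passed in metastasis against primary. With an estimated correlation neither did (adjusted p = 0.694 each).

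Apc fell by 0.77 on the log2 scale in metastasis against primary, and loss of a copy of chromosome 18 was tested as a hypothesis. The 288 tested genes of the chromosome had a median of -0.431. That lies between the -0.5 set as the bound for a lost copy and the -0.25 above which it would be excluded. The median alone leaves it open. Of the 288 genes 79.5% were lower, and 16% changed further downward than Apc. A different dosage of the whole of chromosome 18 predicts a fall along its length, and the 4 parts of 72 genes each, ordered by position, had medians of -0.449, -0.48, -0.4 and -0.382, the highest being -0.382. These values are consistent with a hypothesis of a different dosage of this chromosome in metastasis and primary lines, and copy number was not analysed here. For the fall of Apc between Met1 and Met3 a lost copy is unlikely, as the median of chromosome 18 was -0.0198 there.

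Met2 reps 2 and 3 resembled the Met3 libraries, and shared descent of these 5 lines was tested as a hypothesis through their chromosome shifts. The lowest correlation of chromosome medians among the 5 was -0.204, with a median of 0.13. Between these 5 and the other 10 libraries the median was -0.213 and the highest 0.895. Shared descent may hold for some of them, but these values neither bear it out nor exclude it.

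Chromosome medians of metastasis against primary lay outside all 10000 random sets of as many genes for 14 of 20 chromosomes, among them chromosome 1, with a median of 0.229 over 645 genes.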
